A study of Mus musculus with 3 samples.

How the data were processed

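RNA of microdissected adult mouse renal capsule was measured in 3 samples of 1 group. Per the labels, the mice were male, wild-type CD-1 adults, each sample was the capsule of 1 kidney, samples were not pooled, and RNA went through 1 round of WT-Ovation Pico amplification before biotin labelling. The labels do not state whether the kidneys came from separate animals.

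The deposited table holds log2 values of 35557 probe sets for 3 arrays, from 3.16 to 14.34. The submitters' processing notes name Affymetrix Expression Console without a version. The summary and normalization method, background correction, filters and genome build are not given in the sources used here, and that the values are log2 was read from their range. The columns appear already normalized between arrays, with medians of 7.68, 7.69 and 7.70 and upper quartiles of 8.89, 8.89 and 8.83 for replicates 2, 3 and 4, so a difference in total RNA between samples cannot be seen. Multi-array summaries borrow information across arrays, which can make values of different arrays equal: 10436 probe sets (29.4%) had the same value on all 3 arrays and 9951 (28.0%) on exactly 2. Such genes have a spread that is too small, and their p-values are therefore too small. Scanner output was not used here, so the centring and the scale rest on the deposited values alone.

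Probe sets were named from the platform annotation. Of all probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none listed. Probe sets of the latter kinds were not named. Entrez identifiers of 21698 probe sets matched the RefSeq gene table of mouse assembly GRCm38.p6, which was used for names only and updated 0 symbols. Older list names were matched through its synonyms. Of several probe sets of 1 gene the one with the highest mean was used. This concerned 999 genes, and in 430 of them the probe sets differed by more than 1 log2. Of the 178 genes named in the text, 15 had more than 1 probe set, and in 8 of these the probe sets differed by more than 1 log2: Baiap2l1, Gas5, Hsp90aa1, Hspd1, Piezo1, Piezo2, Ppargc1a and Top2a. No coordinates are given because no genome build is named for the values.

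The table gave 19938 genes. The 1246 sensory receptor genes (olfactory, vomeronasal, taste and trace amine receptors) served as background, and the 95th percentile of their values on an array was its background limit. The other 18692 genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, one-sided) on the log2 value minus the limit of the same array, with Benjamini-Hochberg adjustment and a threshold of 0.05. At an unadjusted p under 0.05, 12064 genes passed. No groups were compared, since the series has 1 group.

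The comparisons, the rule for named genes and 32 gene lists were fixed before the data were examined. The lists hold 419 different genes, of which 383 were measured. They cover fibrillar matrix, fibroblast, embryonic cortical stroma, smooth muscle and pericyte, mesothelium, white and brown fat, endothelium, lymphatic endothelium, macrophage and dendritic cell, lymphocyte, mast cell and granulocyte, erythroid, proximal tubule, thick limb and distal tubule, collecting duct, podocyte, adrenal cortex, skeletal muscle, Schwann cell, immediate early, heat shock, cell cycle, complement and acute phase, interferon response, secreted signals, retinoid, oxidative phosphorylation and liver genes. There are also 3 control lists, of male germ cell, photoreceptor and neuron genes. Members past the test were counted, and the list median was placed among 10000 random lists of the same size. Members without a value of their own were not analysed here.

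Differences between arrays were described without a test. For each list and array, the median over members of the value minus the mean of the other 2 arrays was placed among 10000 random lists matched on mean expression in 20 bins, and a list stood apart outside their central 99%. The erythroid list, with fewer than 3 measured members, was not compared. Pearson's r, Spearman's rho and the SD of the difference were computed for each pair of arrays.

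The genes named in the text follow a rule fixed together with the lists: per list up to 4 members past the test with the largest distance over the limit, or the nearest where none passed; all embryonic cortical stroma members; the 15 brightest genes outside the lists, leaving out gene models and ribosomal or mitochondrial genes; the 10 genes with the widest range over the arrays; up to 4 members of each list that stood apart, in its direction; and the sex-linked genes. Not all genes the rule allows are named. Clec3b, Calb2, Adipoq, Ucp1, Umod, Slc12a1, Fos, Mx1, Cd163, Nphs1, Lum, the Col12a1 difference, Saa3 among the array differences, and the genes of the further families in the closing section were chosen after their values were seen.

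The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The limma step was tested on simulated data with 18692 genes: of genes placed above the limit by 0.1, 0.25, 0.5 and 1 log2 it found 70%, 96%, 96% and 100%, and it called 2% of 200 genes placed at the limit. The list differences were tested on simulated shifts of 0.3 log2 in lists of 14 genes: 10 of 10 shifted lists were found and 1 of 180 values of unshifted lists stood apart. The simulated noise was independent between genes, with spreads shuffled among them. The rate for unshifted lists therefore does not cover lists whose members vary together. The alternatives were background limits at the 90th and 99th percentile, the mean of a gene's probe sets, quantile normalization, subtraction of the median linear background with a floor of 1, limma-trend with robust eBayes, each array over its limit without a model, leaving out dim genes, leaving out each replicate in turn, list means, and single pairs of arrays. Fisher's exact test of each list against the control lists, a floor on the spread, and list differences without equal genes were added after the data were seen.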

Results

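The renal capsule is the thin sheet of connective tissue around the kidney, covered where it faces the body cavity by mesothelium. RNA from capsules pulled off the kidneys of adult male CD-1 mice, an outbred stock, was measured on 3 Affymetrix Mouse Gene ST arrays. All 3 arrays belonged to 1 group, with 1 kidney per sample, no pooling, and no other tissue for comparison. The question the design can answer is which genes and cell types the capsule RNA contained, and how far the 3 dissections were alike. The arrays are named replicates 2, 3 and 4 after their titles. Their median values were 7.68, 7.69 and 7.70 (log2), and the number of arrays limits the precision. Each value with an error is a mean ± SD over n = 3 arrays. Signals of different probe sets carry their own affinities, so the tests compare each gene with the background limit. The percentile of a list among random lists and the choice of bright genes rest on levels of different probe sets, so they describe signal and do not measure how much of a cell type or transcript was present. The labels do not say whether the 3 kidneys came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

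The capsule RNA held transcripts of connective tissue cells, mesothelium and macrophages above background, and 11966 of 18692 genes (64.0%) passed the limma test against the background limit, or 7725 with the limit at the 99th instead of the 95th percentile of its background genes. Bright genes outside the fixed lists included Mgp, which codes for matrix Gla protein, an inhibitor of calcification (13.29 ± 0.10 log2), and Slpi, which codes for a secreted protease inhibitor (13.23 ± 0.10). B2m, the light chain of class I histocompatibility molecules, stood at 13.29 ± 0.11 and the interferon-inducible membrane gene Ifitm3 at 13.22 ± 0.03. The other genes of this group were those of the translation factor Eef1a1, the cytoskeletal genes Actb, Tmsb10 and Myl6, the iron store Fth1, the calcium sensor Calm2, the chaperone Hsp90b1, Tpt1, and the long noncoding RNAs Gas5 and Malat1, between 13.21 and 13.64. The probe set listed under Baiap2l1 reached 13.77 ± 0.05, but its annotation also holds ribosomal RNA records, as does that of a probe set at 12.35 under the same name, and the remaining Baiap2l1 probe set averaged 9.78. The background limit of an array was the 95th percentile of 1246 sensory receptor genes, 7.36 on replicate 2, 7.36 on replicate 3 and 7.46 on replicate 4. Of the 32 measured members of 3 control lists for cell types foreign to a kidney capsule, 5 (15.6%) also passed, so a single gene just over the limit is weak evidence.

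Genes of fibrous connective tissue were above background in nearly all cases. All 19 measured members of the fibrillar matrix list passed the test, and the list's median lay higher than that of all 10000 random lists (percentile 100). Sparc, which codes for a collagen-binding glycoprotein, stood at 13.63 ± 0.23 log2, and the small proteoglycan genes Dcn and Bgn at 13.59 ± 0.04 and 12.26 ± 0.04. Col12a1, a collagen gene of dense connective tissue, stood at 12.08 ± 0.11. Of the fibroblast list, 14 of 15 measured members were above background (percentile 100), among them Dpt at 12.21 ± 0.34, the intermediate filament gene Vim at 11.76 ± 0.14, the growth factor receptor gene Pdgfra at 11.44 ± 0.12 and Gsn at 11.29 ± 0.08. Clec3b was the member that did not pass, at 7.42 ± 0.05 with an adjusted p of 0.506. On replicate 4 the fibrillar matrix list as a whole lay lower than on the other arrays, as described with the array differences.

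Genes that mark the cortical stroma of the embryonic kidney, from which the capsule develops, were all above background in the adult capsule. All 13 measured members of that list passed (percentile 98.2). With no other tissue measured, this does not show that they are particular to that stroma or kept from the embryo. Foxd1, the transcription factor that marks stromal progenitors, read 10.53 on each array, 3.14 log2 above the limit (limma adjusted p = 5.15e-07). Smoc2 (12.23 ± 0.04), Sfrp1 (11.70 on each array), Meis1 (10.99 ± 0.03) and Meis2 (10.87 on each array) were also far over the limit. Rdh10 and Aldh1a2, enzymes of retinoic acid synthesis, stood at 9.87 ± 0.17 and 9.10 ± 0.38, and the transcription factor gene Tcf21 at 8.97 ± 0.14. Ntn1 read 8.92 on each array, Dlk1 stood at 8.46 ± 0.21 and the cadherin gene Fat4 at 8.42 ± 0.07. Crabp1 and Tbx18 passed by small margins, 0.29 and 0.22 log2 (adjusted p = 0.000651 and 0.00611), and both lay under the limit when it was set at the 99th percentile of the sensory receptor genes.

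Mesothelial genes were well above background. Of 14 measured members 13 passed (percentile 100). The membrane glycoprotein gene Gpm6a stood at 13.14 ± 0.10 log2, the uroplakin genes Upk1b and Upk3b at 12.21 ± 0.45 and 11.70 ± 0.28, and Msln, which codes for mesothelin, at 11.22 ± 0.54. Calb2, the calretinin gene often used to stain human mesothelium, was the exception at 5.72 on each array, under the limit. This gene was chosen after its values were seen.

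**Figure D1:**
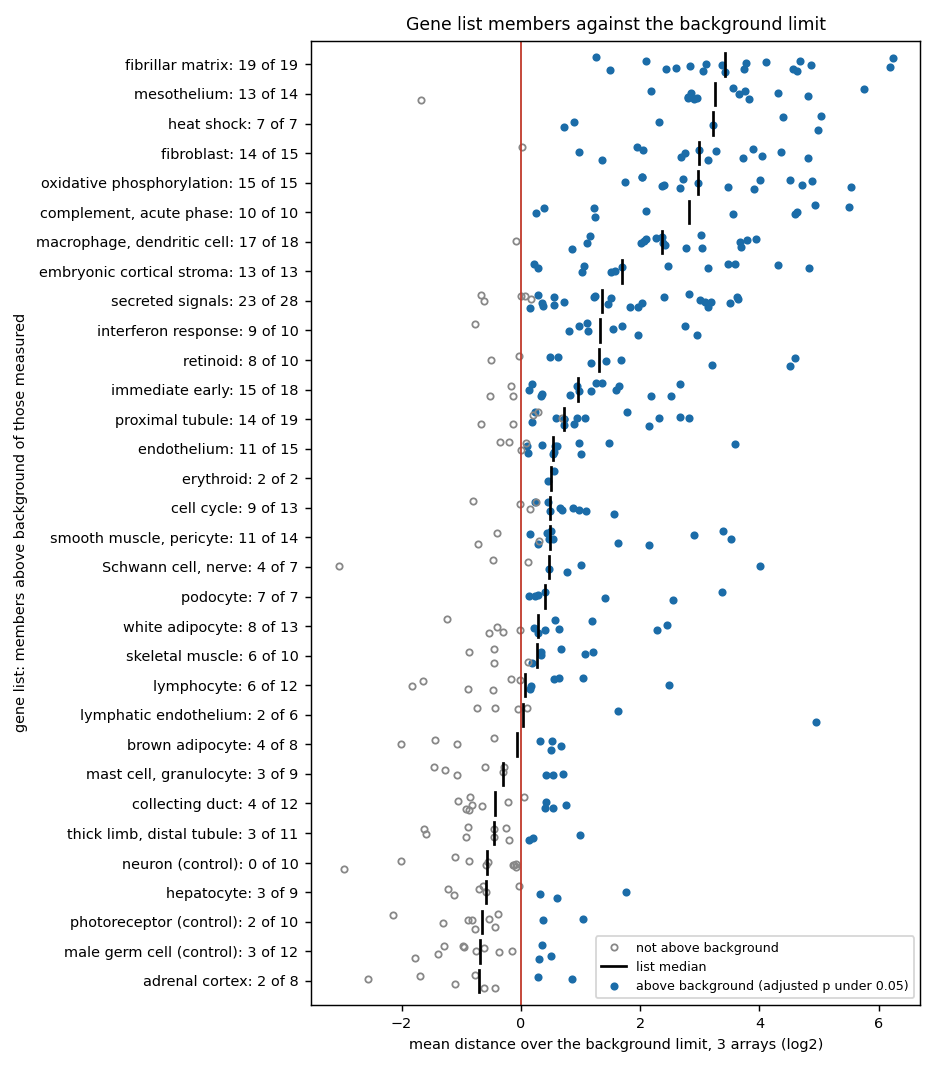
Mean distance of each list member over the background limit (log2, x axis, 3 arrays) by gene list (y axis). Filled points passed the limma test, open points did not, black bars are list medians and the red line is the limit. Fibrillar matrix (19 of 19), mesothelium (13 of 14) and fibroblast (14 of 15) members lie to the right, while neuron (0 of 10) members all lie to the left of the line.

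Vessel, muscle and fat genes were above background in part. Of the smooth muscle and pericyte list 11 of 14 members were above background (percentile 40.4), led by the contractile genes Acta2 (10.92 ± 0.32 log2), Tagln (10.78 ± 0.08), Mylk (10.30 ± 0.13) and Smtn (9.55 on each array). Of the endothelial list 11 of 15 passed (percentile 44.2), with the VEGF receptor gene Kdr at 10.99 ± 0.14, the cadherin gene Cdh5 at 8.87 ± 0.54, Ehd3 at 8.41 and Egfl7 at 8.38. In the lymphatic list 2 of 6 passed (percentile 19.2): Pdpn, which mesothelial and fibroblast-like cells also express, at 12.35 ± 0.32, and Lyve1, which some macrophages also express, at 9.03 on each array. Of the white fat list 8 of 13 passed (percentile 26.1). They included the lipid-handling genes Lpl (9.85 ± 0.28), Cd36 (9.68 ± 0.20) and Fabp4 (8.58 ± 0.04), and Thrsp (8.04 ± 0.03), whereas Adipoq, the fat cell hormone gene, stood at 6.86 ± 0.07 and did not. Of the brown fat list 4 of 8 passed (percentile 11.4), with Ppargc1a at 8.07 on each array and Cox8b at 7.91 ± 0.07, but Ucp1, the uncoupling protein of brown fat, stood at 6.32 ± 0.08, under the limit. The counts of the smooth muscle, endothelial, white fat and brown fat lists dropped to 5, 4, 3 and 0 with the limit at the 99th percentile.

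Macrophage and dendritic cell genes were well above background. Of 18 measured members 17 were above background (percentile 100), with the class II gene H2-Aa at 11.34 ± 0.67 log2, the lysozyme gene Lyz2 at 11.19 ± 0.42, the lysosomal protease gene Ctss at 11.09 ± 0.37 and the mannose receptor gene Mrc1 at 11.08 ± 0.16. Itgax, a dendritic cell integrin gene, did not pass at 7.31 ± 0.43. Of the lymphocyte list 6 of 12 members passed (percentile 12.5), among them the pan-leukocyte gene Ptprc at 9.88 ± 0.60, the T cell receptor complex genes Cd3g at 8.43 ± 0.79 and Cd3e at 8.04 ± 0.33, and Nkg7 at 7.95 ± 0.64. Both lists lay higher on replicate 4 than on the other arrays. Of the mast cell and granulocyte list 3 of 9 passed (percentile 4.86), all 3 being mast cell protease genes: Mcpt4 (8.10 ± 0.29), Cpa3 (7.94 ± 0.14) and Tpsb2 (7.82 on each array). Only 2 erythroid genes were measured on probe sets of their own, Alas2 at 7.96 on each array and Slc4a1 at 7.85 ± 0.04, and both passed (percentile 45.1). With the limit at the 99th percentile the lymphocyte, mast cell and erythroid counts were 2, 0 and 0.

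Markers of kidney tubules were unequal. Of the proximal tubule list 14 of 19 members were above background (percentile 62.7), with the endocytic receptor gene Lrp2 at 10.22 ± 0.35 log2, the creatine synthesis gene Gatm at 10.07 ± 0.10, Kap, an androgen-regulated gene of the proximal tubule, at 9.72 ± 2.23 and the water channel gene Aqp1 at 9.55 ± 0.07. Kap passed on its mean but read 7.2 on replicate 4, under the limit of that array. The proximal tubule list also differed between arrays, and its count was 7 with the limit at the 99th percentile. Its leading members did not share that difference alike. Against the mean of the other arrays, replicate 4 stood at -3.774 for Kap, -0.594 for Lrp2, -0.116 for Aqp1 and 0.095 for Gatm. Of the thick limb and distal tubule list 3 of 11 passed (percentile 1.64), Ptger3 at 8.40 and, by small margins, Slc12a3 at 7.59 and Egf at 7.54, each equal on the 3 arrays. Umod and Slc12a1, abundant transcripts of the thick ascending limb, stood at 7.15 ± 0.07 and 5.78 and did not pass. The count of this list was 1 without replicate 2 and 1 without replicate 3. Of the collecting duct list 4 of 12 passed (percentile 0.96), with the water channel genes Aqp2 at 8.15 ± 0.09 and Aqp3 at 7.80 ± 0.01, Fxyd4 at 7.93 ± 0.07 and the vasopressin receptor gene Avpr2 at 7.82 ± 0.16. None of these 4 passed with the limit at the 99th percentile.

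All 7 measured members of the podocyte list passed (percentile 38.7). Its leading members were Npnt at 10.77 ± 0.30 log2, the cell cycle inhibitor gene Cdkn1c at 9.95 ± 0.02 and Clic3 at 8.81 ± 0.42, which other cell types also express, while Synpo stood at 7.80 ± 0.03. Nphs1, the nephrin gene of the podocyte slit diaphragm, named after its values were seen, was 0.28 log2 above the limit (adjusted p = 0.00119). For tissues next to the kidney, 2 of 8 adrenal cortex members passed (percentile 0.88), Star at 8.26 ± 0.02 and Nr5a1 at 7.69, and 6 of 10 skeletal muscle members passed (percentile 25.1), including Tnnt3 at 8.61 ± 0.03, Ckm at 8.48 ± 0.04 and Acta1 at 8.06. Of the Schwann cell and nerve list 4 of 7 passed (percentile 42.3): Pmp22, a myelin gene that fibroblasts also express, at 11.40 ± 0.13, Mbp at 8.40 ± 0.03, the sodium channel gene Scn7a at 8.17 ± 0.29 and Sox10 at 7.87 ± 0.003. Of the liver list 3 of 9 passed (percentile 1.34), Cyp2e1 at 9.16 ± 1.27, Apoa2 at 7.998 and Apoa1 at 7.72. Cyp2e1 fell from replicate 2 to 3 to 4, an order that the proximal tubule genes Kap and Slc27a2 also followed, so its source is open. The podocyte, adrenal, skeletal muscle, Schwann cell and liver counts were 3, 0, 2, 2 and 1 with the limit at the 99th percentile.

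In the control lists, 3 of 12 male germ cell genes passed (percentile 0.32), with Gapdhs at 7.89 ± 0.01 log2 and Prm2 at 7.75 ± 0.04. Of the photoreceptor genes 2 of 10 passed (percentile 0.56), Rom1 at 8.44 ± 0.08 and Prph2 at 7.77 ± 0.02. None of the 10 neuron genes passed the limma test, adjusted or at an unadjusted p under 0.05 (percentile 0.95), the closest being Slc32a1 at 7.31, and 4 passed with the limit at the 90th percentile. Set against the 3 control lists together, 19 of the other 29 lists had a larger share of members above background (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p from 2.54e-08 for fibrillar matrix to 0.0167 for skeletal muscle). The Fisher test did not separate 10 lists from the control lists: adrenal cortex (adjusted p = 0.611), thick limb and distal tubule (0.415), liver (0.367), mast cell and granulocyte (0.367), lymphatic endothelium (0.351), collecting duct (0.275), brown fat (0.0749), lymphocyte (0.0595), erythroid (0.0517) and Schwann cell (0.0517). Of all tested genes 64.0% passed the limma test, against 15.6% of the control list members. A list can thus pass the Fisher test without exceeding the share of genes in general. The white fat and skeletal muscle shares lay below 64.0%. The Fisher comparison runs across genes, which are not independent replicates, and was chosen after the counts were seen. Skeletal muscle no longer passed it without replicate 2 or without replicate 3, and the endothelial, white fat, cell cycle and skeletal muscle lists did not pass it with the limit at the 99th percentile. With the 90th percentile white fat and skeletal muscle did not pass, and in 4 settings the Schwann cell list did.

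Genes of cell programmes were above background in most cases. All 15 oxidative phosphorylation genes passed (percentile 100), among them Cox6c at 12.94 on each array, Ndufa4 at 12.28 ± 0.12 and Atp5b at 12.12 ± 0.16 log2. All 7 measured heat shock genes passed (percentile 99.98), with the mitochondrial chaperone genes Hspe1 at 12.44 ± 0.05 and Hspd1 at 11.80 ± 0.09 and the cytosolic Hsp90aa1 at 12.39 ± 0.03. Of the immediate early genes, which cells switch on within minutes of a stimulus such as handling, 15 of 18 passed (percentile 81.6). Ccn1 stood at 10.06 ± 0.31, Klf6 at 9.92 ± 0.04 and Btg2 at 9.57 ± 0.01, whereas Fos read 7.26 on each array and did not pass. Of the cell cycle genes 9 of 13 passed (percentile 41.0), with Top2a at 8.95 ± 0.40, Birc5 at 8.49 ± 0.05, Ccnb2 at 8.38 ± 0.43 and Cdk1 at 8.27 ± 0.56, and 3 passed with the limit at the 99th percentile.

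Many complement, interferon-induced, secreted signal and retinoid genes were also above background. All 10 measured complement and acute phase genes passed (percentile 100). Serping1, which codes for the C1 inhibitor, stood at 12.89 ± 0.01 log2, the alternative pathway gene Cfb at 12.33 on each array, the classical pathway protease gene C1s1 at 12.03 ± 0.19 and the acute phase gene Saa3 at 11.996 ± 0.94. Of the interferon-induced genes 9 of 10 passed (percentile 90.9), with Oasl2 at 10.35 ± 0.27, Ifit3 at 10.16 ± 0.01 and Ifit2 at 9.37 ± 0.12, and Mx1 did not, at 6.63 on each array. Of the secreted signals 23 of 28 passed (percentile 98.6), with Bmp4 at 11.04 ± 0.11, the alarmin gene Il33 at 11.03 ± 0.02, Igf1 at 10.91 ± 0.11 and the Wnt modulator gene Sfrp2 at 10.58 ± 0.81. Of the retinoid genes 8 of 10 passed (percentile 90.3), with the retinal dehydrogenase gene Aldh1a1 at 11.99 ± 0.01, the retinal reductase gene Dhrs3 at 11.91 ± 0.15 and Rbp4, which codes for the retinol carrier, at 10.59 ± 0.59. All these counts rest on Benjamini-Hochberg adjustment over the 18692 genes. The counts adjusted over the list alone were the same for 30 of the 32 lists, with 4 rather than 6 lymphocyte genes and 5 rather than 4 Schwann cell genes.

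Several gene lists differed between the 3 arrays, and dissection, amplification and hybridization are not separated here. Proximal tubule genes lay lower on replicate 4, by a list median of -0.44 log2 against the mean of the other arrays, and higher on replicate 2, by 0.51. Kap read 11.44, 10.51 and 7.2 on replicates 2, 3 and 4, the fatty acid transporter gene Slc27a2 read 10.40, 9.71 and 7.42, and Miox, an inositol oxygenase gene of the proximal tubule, read 8.82, 7.93 and 6.03. On replicate 4, 12 of the 19 proximal tubule genes lay over 0.2 log2 lower and 0 lay that much higher. Macrophage and dendritic cell genes lay higher on replicate 4, by 0.53, and so did lymphocyte genes, by 0.44. Of 18 macrophage and dendritic cell genes 15 lay over 0.2 log2 higher there, and 1 lay that much lower: Cd163, a scavenger receptor gene chosen after its values were seen, read 8.89, 8.55 and 8.09. The invariant chain gene Cd74 read 9.74, 9.88 and 11.62, the class II gene H2-Ab1 read 9.16, 9.30 and 10.83, and Cd3g read 7.82, 8.15 and 9.33. With 1 array against 2 there is no test, so these differences describe these arrays.

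Connective tissue and mesothelial genes also lay lower on replicate 4. The list medians were -0.36 log2 for fibrillar matrix and -0.42 for mesothelium. Random lists matched on mean expression ranged from -0.238 to 0.0 and from -0.262 to 0.003 on replicate 4, respectively. Lists of equally bright genes thus also tended lower on that array. Both medians lay below these ranges, but part of each drop may be shared with other bright genes. Fn1, the fibronectin gene, read 10.37, 10.01 and 8.13 on replicates 2, 3 and 4, Postn, the periostin gene, read 10.66, 10.24 and 8.59, and Krt8, a keratin gene of mesothelium, read 10.54, 10.54 and 9.53. Lum, the lumican gene, went the other way and lay 0.88 higher on replicate 4, and so did Col12a1 by 0.18. Cell cycle genes lay lower on replicate 4 by -0.30, with Cdk1 at 8.57, 8.61 and 7.62, and interferon-induced genes by -0.24, with Rsad2 at 8.30, 8.52 and 7.81, a list difference that no longer stood apart with list means, among genes above background alone, against replicate 2 alone or without equal genes. Smooth muscle genes lay higher on replicate 4 by 0.23, with Acta2 at 10.79, 10.69 and 11.28, and complement genes by 0.08, with Lcn2 at 8.34, 8.42 and 9.19 but Saa3 at 12.50, 12.57 and 10.91. The complement difference no longer stood apart on any array with list means. The fibroblast list stood at -0.23 on replicate 4, inside the range of random lists.

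The same contrast, read from the other arrays, put fibrillar matrix at 0.245 on replicate 2 and 0.14 on replicate 3, fibroblast genes at 0.17 on replicate 2, mesothelium at 0.27 on replicate 3, and cell cycle genes at 0.24 and 0.08 on replicates 2 and 3. Macrophage genes stood at -0.20 and -0.32 there, lymphocyte genes at -0.23 and -0.20, smooth muscle genes at -0.11 and -0.06, and complement genes at -0.045 and -0.04, which stood apart on neither with quantile normalization or against each other. The lymphatic list stood at -0.09 on replicate 2 and 0.16 on replicate 3, with Mmrn1 at 7.203, 7.72 and 7.59, but stood apart on neither with list means or against single arrays. In total 26 of 93 values from 31 lists lay outside the central 99% of 10000 random lists matched on mean expression. These 26 values came from 11 lists. For lists of unrelated genes chance gives 0.93. The 3 values of a list are not independent, and members of marker lists may vary together, so the 2 numbers do not measure the strength of evidence. The other 20 lists stood apart on none, although mast cell, retinoid and liver genes did in other settings. Endothelium and embryonic cortical stroma were among the 20 with medians of 0.00, to which members equal on all arrays contribute. On replicate 4, 3 of 15 endothelial genes lay over 0.2 log2 lower and 0 higher, and 3 of 13 embryonic stroma genes lay lower and 1 higher. Replicates 2 and 3 set directly against each other turned the sign for fibrillar matrix on replicate 3 (-0.06), macrophage genes on replicate 2 (0.08) and cell cycle genes on replicate 3 (-0.02).

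**Figure D2:**
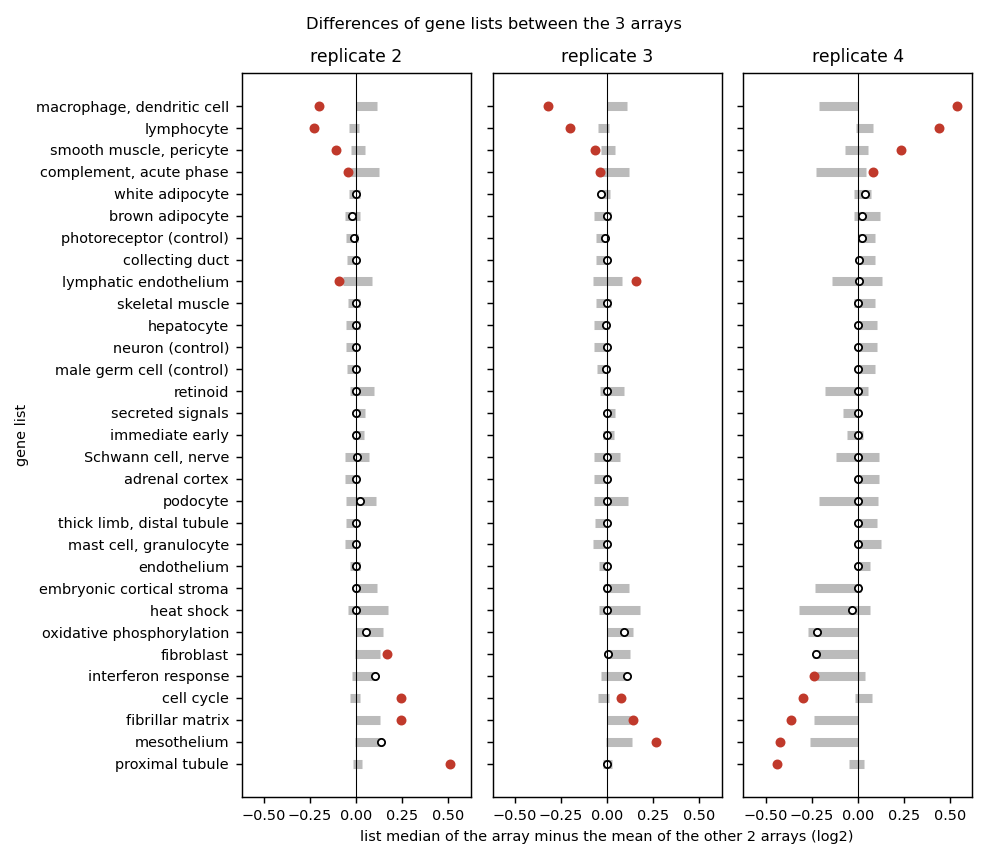
Median difference of each gene list (y axis) between 1 array and the mean of the other 2 (log2, x axis), 1 panel per replicate. Grey bars span the central 99% of 10000 random lists matched on mean expression, red points lie outside it and open points inside. On replicate 4 macrophage genes stand at 0.53 and proximal tubule genes at -0.44.

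**Figure D3:**
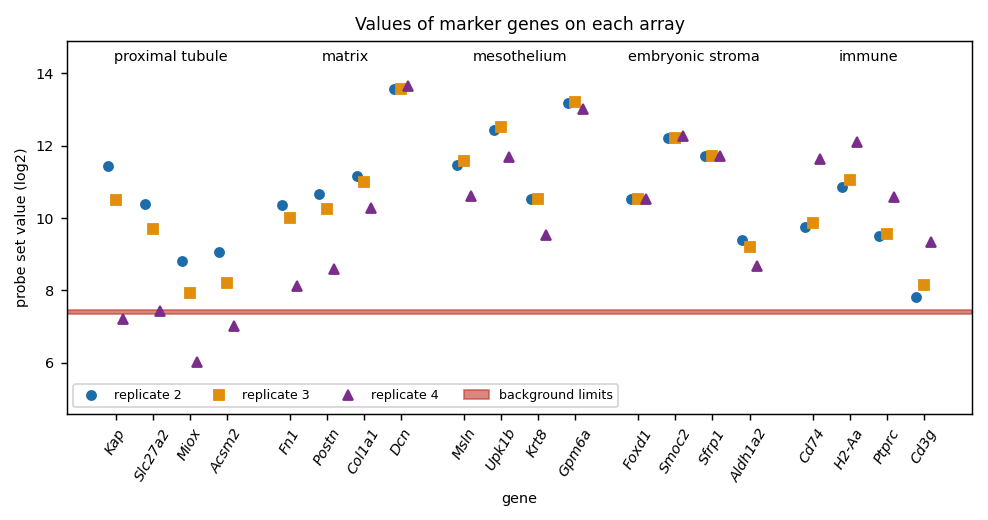
Probe set values (log2, y axis) of 20 marker genes (x axis) on replicates 2, 3 and 4, with the band of the 3 background limits. Kap, Fn1 and Msln lie lowest on replicate 4, Cd74 lies highest there, and Foxd1 reads 10.53 on all arrays.

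Among the single genes with the widest range, most were lower on replicate 4. Ugt2b38, a glucuronosyltransferase gene, read 10.14, 8.47 and 5.65 log2 on replicates 2, 3 and 4, Cyp2j5 read 9.46, 8.54 and 6.32, Keg1 read 9.97, 8.97 and 6.83, and Cltrn read 8.74, 7.80 and 6.33. Cyp2e1 read 10.44, 9.12 and 7.91. Scrg1 followed another order, with 9.77, 9.89 and 6.68, and Jchain, which joins antibody chains in plasma cells, read 5.32, 5.15 and 8.74. Of these genes Cyp2e1 passed the test against background, and Ugt2b38, Cyp2j5, Keg1, Cltrn, Scrg1 and Jchain did not, nor did Miox. Across genes above background, which are not independent replicates, Pearson's r was 0.998 between replicates 2 and 3 but 0.980 and 0.981 between replicate 4 and each of them. Spearman's rho was 0.997, 0.974 and 0.974 for the same pairs. The SD of the difference was 0.077 log2 for replicates 2 and 3, 0.225 for 2 and 4, and 0.224 for 3 and 4. Among genes above background, 23 lay over 1 log2 higher and 40 over 1 log2 lower on replicate 4 than on the mean of the others.

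The labels give male mice, and sex-linked genes fitted that on each array. Xist, which is transcribed from the inactive X chromosome of females, stood at 5.90 ± 0.05 log2, under the limit. The Y-linked genes Eif2s3y (9.61 ± 0.07), Kdm5d (9.47 ± 0.33) and Uty (8.47 ± 0.03) were above background. Ddx3y was not analysed here. Many probe sets had exactly the same value on several arrays, 29.4% on all 3 and 28.0% on exactly 2 of them, so an SD of 0 understates the spread of those genes.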

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

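No test was run for the values below, and the globin probe sets were chosen only after their values were seen. Signal was present in probe sets that the comparisons did not use. Of 12147 probe sets without a listed gene, 5006 (41.2%) lay above the background limit on all 3 arrays, and of 1621 probe sets shared by several genes, 882 (54.4%) did. These probe sets are named for no gene here, so what they measure was left open. Among the shared ones were 4 probe sets of the haemoglobin gene copies, which the erythroid list could not use. The alpha globin pair read 10.67, 10.94 and 9.82 log2 and 10.54, 10.80 and 9.68 on replicates 2, 3 and 4, and the beta globin pair read 11.65, 11.87 and 10.81 and 11.75, 12.05 and 10.96. All 4 were above the limits on each array and lowest on replicate 4. With 3 arrays in the group, no single array was tested as an outlier.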

How the results depend on the processing

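The floor on the spread, list differences without equal genes and all values of Fisher's exact test were chosen only after the data were seen. No paired analysis was possible because there is 1 group. Signal over background limits what the arrays can show for dim genes, and the number of arrays limits precision.

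With the limit at the 99th percentile, 7725 genes passed. The list counts were smooth muscle 5, white fat 3, brown fat 0, endothelium 4, lymphocyte 2, mast cell and granulocyte 0, erythroid 0, proximal tubule 7, thick limb and distal tubule 1, collecting duct 0, podocyte 3, adrenal cortex 0, skeletal muscle 2, Schwann cell 2, cell cycle 3, liver 1, male germ cell 0 and photoreceptor 1. With the 90th percentile the lymphatic count was 4, thick limb and distal tubule 5 and neuron 4. A higher or lower limit shifts every gene by construction. With dim genes left out, which removes members by construction, the counts were smooth muscle 5, white fat 4, brown fat 1, endothelium 5, lymphocyte 3, mast cell and granulocyte 1, erythroid 0, thick limb and distal tubule 1, collecting duct 1, podocyte 3, adrenal cortex 1, skeletal muscle 3, male germ cell 0 and photoreceptor 1. The thick limb and distal tubule count was 1 with the floor on the spread, and 1 to 3 with 1 replicate left out.

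Under the 99th percentile these genes lay under the limit (log2): Tbx18 -0.45, Crabp1 -0.385, Lmod1 -0.23, Thrsp -0.034, Ppargc1a -0.003, Cox8b -0.158, Cd3e -0.031, Nkg7 -0.117, Cpa3 -0.131, Tpsb2 -0.249, Alas2 -0.109, Slc4a1 -0.22, Slc12a3 -0.477, Egf -0.532, Fxyd4 -0.142, Avpr2 -0.252, Aqp3 -0.273, Synpo -0.271, Nr5a1 -0.383, Acta1 -0.007, Sox10 -0.202, Apoa2 -0.071, Apoa1 -0.348, Gapdhs -0.175, Prm2 -0.32, Prph2 -0.303, Nphs1 -0.39. With the mean of its probe sets Ppargc1a lay at -0.128.

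The following array differences (log2) no longer stood apart or turned, and why was not tested. Replicates 2 and 3 against each other gave -0.059 for fibrillar matrix on replicate 3, 0.0 for smooth muscle, lymphocyte and complement genes on either array, 0.022 for mesothelium on replicate 3, -0.038 and 0.038 for the lymphatic list on replicates 2 and 3, 0.081 for macrophage genes on replicate 2 and -0.017 for cell cycle genes on replicate 3. Against replicate 4 the lymphatic list gave -0.064 and 0.12 on replicates 2 and 3. With list means it gave -0.061 and 0.13, complement genes gave -0.018, -0.053 and 0.071 on replicates 2, 3 and 4, and interferon-induced genes -0.25 on replicate 4. With quantile normalization complement genes gave -0.042 and -0.049 on replicates 2 and 3. Among genes above background alone, cell cycle genes gave 0.053 on replicate 3 and interferon-induced genes -0.262 on replicate 4. The latter gave -0.198 against replicate 2 and -0.297 without equal genes.

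The count of genes above background lay between 9340 and 13835 in the other alternatives with all arrays, and between 11168 and 12407 with 1 replicate left out.

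Under the settings chosen in advance, with all arrays, list counts stayed within 1.5 times in 221 cases and moved further in 35, and differences that stood apart still did so with the same direction in 155 cases, no longer did in 22 and turned in 3. Differences inside the range of random lists lay outside it in 17 cases, and in 1 more without equal genes. They belonged to the fibroblast, mesothelium, mast cell, proximal tubule, interferon, retinoid and liver lists. Named genes kept their side of the test in 1329 cases, lost the call in 22, gained it in 7 and turned in 28. With 1 replicate left out they kept it in 517, lost it in 7 and gained it in 10. The number of lists past Fisher's exact test lay between 15 and 20. Skeletal muscle also failed it with dim genes left out and with the floor on the spread. The Schwann cell list passed it with probe set means, limma-trend, no model and dim genes left out.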

Other observations

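The gene families in the first paragraphs were chosen after their values were seen. Of all tested genes 64.0% passed the limma test, and the claudin, keratin and steroid receptor shares lay below that. Of the tests of explanations, the median polish simulation was chosen before its result was seen and the others after.

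Hox genes, which record position along the body axis, were widely above background. Of the measured genes of paralogue groups 1 to 11, 27 of 31 passed the limma test, while 0 of 6 of groups 12 and 13 did (Fisher's exact test, p = 9.03e-05). The division was chosen after the values were seen, so this p-value is no independent support for it. Hoxc9 stood at 9.72 ± 0.15 log2 and Hoxb5 at 9.37. Epithelial junction and filament genes were above background in part, with 12 of 23 claudins and 14 of 48 keratins. Cldn1, which codes for a tight junction protein, stood at 10.44 ± 0.35 and Cldn15 at 9.24 ± 0.01, and among keratin genes Krt7 stood at 11.02 ± 0.44, Krt19 at 10.96 ± 0.38, Krt18 at 9.57 ± 0.29 and Krt14 at 9.32 ± 0.65. With the limit at the 99th percentile 17 Hox genes of groups 1 to 11, 5 claudins and 6 keratins passed. Of the keratins 26 passed with the 90th percentile, and with dim genes left out 9 keratins and 5 claudins did.

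Members of some signalling families were above background. All 7 class 3 semaphorin genes, which code for secreted guidance cues, were above background, with Sema3c at 11.95 ± 0.24 log2 and Sema3a at 9.70 ± 0.60. Of the IGF binding protein genes 6 of 7 passed, with Igfbp5 at 12.58 ± 0.04 and Igfbp6 at 12.48 ± 0.08, and Igfbp1 did not, at 6.999 ± 0.063. All 4 latent TGF-beta binding protein genes passed. Of the steroid receptor genes 2 of 5 passed, the oestrogen receptor gene Esr1 at 9.90 ± 0.04 and the glucocorticoid receptor gene Nr3c1 at 9.90 ± 0.10. Both Piezo genes, which code for stretch-gated channels, and 3 of 4 angiotensin genes passed, the latter 1 of 4 with the limit at the 99th percentile. Agt was the angiotensin gene that did not pass, at 7.21 on each array.

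Proximal tubule genes differed between the arrays. After quantile normalization the list still lay at -0.442 log2 on replicate 4, against -0.439 before. The deposited columns were already near equal in distribution, so that step could change little and cannot decide on a shift of the whole array. Random lists matched on mean expression had a range of -0.046 to 0.032 on replicate 4. Genes of similar level thus did not share the difference of the proximal tubule list. Different amounts of carried-over tubule may be the source. Of 12 members with both differences, 66.7% had a ratio of linear differences within 1.5 times the median of 2.09, under the 75% set for a single source, though 0 of 19 members lay over 0.2 log2 higher on replicate 4, so this stays open. No biological explanation was tested.

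Macrophage and lymphocyte genes lay higher on replicate 4, where a lower share of stroma and mesothelium would raise other cell types alike. Among members over 1 log2 above the limit, 16 macrophage genes had a mean difference of 0.572 log2. In contrast, 3 endothelial genes had -0.391 (0 of 3 higher, permutation p = 0.0186), and these with 5 smooth muscle genes had 0.002 (permutation p = 0.0214, across genes). The 5 smooth muscle genes alone, at 0.237, were not separated (permutation p = 0.225), while all 11 above background, at 0.188, were (permutation p = 0.0406). The endothelial genes thus did not rise as this explanation needs. The smooth muscle genes rose, though all 11 together rose less than the macrophage genes. Lists of other cell types moved unequally. Their members above background had mean differences of -0.702 for proximal tubule, 0.011 for white fat, 0.113 for collecting duct and 0.771 for lymphocyte genes. With 3 endothelial genes, of which Ehd3 was equal on all arrays, and a macrophage list picked for its rise, this stays open. Class II alleles of outbred mice that bind probes unequally could change H2 signals alone. The 27 members outside the H2 genes had a median of 0.381 with 25 of 27 higher, which such alleles would leave unexplained. Both lists were picked for their rise, and only 3 of their members are H2 genes. Leaving these out could change the median little, so this check is no independent test of alleles. For the 3 H2 genes, with a median of 1.149, alleles, more cells and other causes cannot be told apart. Neither genotypes nor cell numbers were used here. Macrophage list members outside the H2 genes rose unequally on replicate 4, with 14 of 15 higher. The invariant chain gene Cd74 stood at 1.815 there, Mrc1 at 0.25 and Cd163 at -0.63. Mrc1 and Cd163 were picked here after their values were seen. No other explanation was tested.

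Many probe sets had the same value on several arrays. Median polish over an odd number of arrays is a candidate explanation: in 2000 simulated probe sets with 25 probes each, an assumed number, and no difference between arrays, 78.1% came out equal on all 3 arrays and 0.0% with 4 arrays. With 3 arrays a further 19.2% had 2 values. The deposited table had 29.4% equal on all 3 and 28.0% on exactly 2. The simulation thus shows that such ties can arise and does not account for their number. The method that made the deposited values is not given in the sources used here. No biological explanation was tested.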
